A study of Mus musculus with 6 samples.

How the data were processed

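RNA was sequenced from CD45-low CD11b-positive microglia of 6 libraries, 3 from mice given the control antibody and 3 from mice given the anti-LILRB4 antibody, with groups and replicate numbers taken from the sample titles. Per the labels' protocols, cDNA was made from total RNA with a low-input kit that does not mark strand, so reads of a gene and of an overlapping antisense gene cannot be told apart.

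The deposited count table holds whole read counts per Ensembl gene, not normalized, and the submitters' processing notes name STAR, Subread featureCounts, Salmon and DESeq2 1.38.3 without their roles. The genome build, the annotation and the handling of reads that match several genes are not given in the sources used here. Genes with near-identical copies (Ifit, Ifi200, H2, mitochondrially encoded and LILR genes) are therefore uncertain in the split of their reads. A second table deposited by the authors gives a log2 fold change, its standard error, a score (the ratio of the fold change to its error), a p-value and adjusted p-value, and a mean normalized count per gene. Per the file headers these columns are those of DESeq2. The authors' coordinates had the same chromosome and start as GENCODE M21 (GRCm38) for 499 of 24360 genes (2.05%), so all coordinates printed are those of GENCODE M21 on GRCm38, joined by Ensembl identifier. These coordinates do not bear on the counts.

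Among the deposited counts, 287 rows repeated an identifier with identical counts and were dropped, which left 55493 genes, 6 of them human LILR transgene rows. Total counts per library were between 39805118 and 56345514. One locus, CT010467.1, took 6.62% of counts on average. No pair of libraries agreed within sampling noise. The main test was edgeR 4.0.16 (R 4.3.3) with filterByExpr at its default minimum count of 10, TMM normalization and the quasi-likelihood F test of treatment with no covariate, on 18210 genes. Genes were called at a Benjamini-Hochberg adjusted p of 0.05. CPM values use TMM library sizes, and log2 CPM a prior count of 2. Log2 fold changes are treated minus control, and their standard errors are the fold change divided by the square root of F. DESeq2 1.42.0 with independent filtering at 0.05 and voom in limma 3.58.1 were run as alternatives.

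Before the data were examined, 4 primary gene lists, 13 secondary lists and 11 lists of markers of other cell types were fixed. The 27 lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, adjusted over the 27 lists, and again with an estimated correlation and with fry, whose p-value tests the list's own genes and not against other genes. Camera called 11 lists, 9 lower and 2 higher, 0 of them with an estimated correlation (smallest adjusted p 0.0996) and 0 with fry (smallest adjusted p 0.0816). List levels are the mean log2 CPM of the members per library. A 3 against 3 permutation of levels has 10 splits and cannot go below 0.1.

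The genes named were fixed by rule before the data were examined. They were 6 per direction with the largest change among called genes whose groups did not overlap and whose mean log2 CPM was at least 2, the 3 with the smallest p of each primary list, 1 of each secondary list, the 2 most abundant of each other cell type list used in the text, and Lilrb4a, Lilrb4b, Apoe, Trem2 and Tyrobp. As 0 genes were called, the places were filled by the smallest unadjusted p, with the limits on overlap and abundance kept. A literal reading of the fill without those limits would have named other genes as well. Predicted genes and pseudogenes were skipped. The result for 1 gene is not reported here. The transgene rows were added because the antibody binds LILRB4.

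The tests were checked on counts simulated from the real means, library sizes and dispersions of this comparison, with 200 genes changed. In 17486 genes edgeR recovered 65% of 100 genes changed by 1 on the log2 scale and 97% of 100 changed by 2, with 14 false calls. DESeq2 recovered 82% and 100%, with 59 false calls. With no gene changed, among 17455 genes, edgeR made 0 false calls and DESeq2 4. A length trend put into 17417 simulated genes gave a rank correlation of fold change with length of 0.477, which the length and GC correction brought to 0.0233.

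Alternatives fixed before the data were examined were DESeq2 size factors, library size only and upper quartile scaling, DESeq2, limma-voom, no filter, a CPM of at least 1 in 3 libraries, a replicate block, leaving out each library, robust dispersion, protein-coding genes only, an adjusted p of 0.1 and an absolute log2 fold change of at least 0.5. Chosen after seeing the data were a length and GC correction (per-library splines with 4 degrees of freedom entered as offsets, values for 99.8% of tested genes), DESeq2 on genes with at least 10 reads, permutation of list levels, and a neutrophil marker covariate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.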

Results

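Gene expression was measured by RNA sequencing in microglia, the resident macrophages of the brain, sorted as CD45-low CD11b-positive cells from male mice that carried a human LILR-region transgene (named ILT Telo Tg in the labels) on the 5XFAD background, an amyloid model of Alzheimer disease. The mice were 4 months old at the start and received 8 weekly intraperitoneal injections at 60 mg/kg of an Fc-mutant antibody against human LILRB4 (also called ILT3, an inhibitory receptor of myeloid cells) or of an Fc-mutant control antibody. The comparison asks how blocking LILRB4 in vivo changed the microglial transcriptome. There were 3 libraries per group. Total counts were 44987032, 39805118 and 44496830 in control libraries 1, 2 and 3 and 44369561, 56345514 and 41948140 in anti-LILRB4 libraries 1, 2 and 3. The labels do not state that the libraries came from separate animals, so p-values measure the spread between these libraries.

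In the libraries of anti-LILRB4-treated mice, interferon-response and disease-associated microglia genes were at lower levels than in controls and homeostatic microglia genes at higher levels, as groups in a list test with a preset correlation. With an estimated correlation none of these 3 lists was called (adjusted p 0.376 each). At the preset correlation neutrophil markers (median log2 fold change -0.88), mitochondrially encoded genes (-0.42) and immediate early and dissociation genes (-0.25) were also called lower. With an estimated correlation these were not called either (adjusted p 0.486, 0.376 and 0.0996). The mean neutrophil marker level of anti-LILRB4 library 2 (-0.13, log2 relative to the control mean) lay above those of control libraries 2 and 3 (-0.42 and -0.22). Among genes whose groups did not overlap and whose mean log2 CPM was at least 2, those lower with the smallest p-values were Kcnj2, an inward-rectifier potassium channel, Cd63, a tetraspanin of late endosomes, Axl, a receptor tyrosine kinase for apoptotic cells, mt-Cytb, a subunit of respiratory complex III, and the interferon-response genes Usp18 and Ifitm3. Those higher were Gatad2a, a subunit of a chromatin-remodelling complex, Cd276, an immune checkpoint ligand, Cirbp, a cold-inducible RNA-binding protein, Cd74, the MHC class II invariant chain, Tnfrsf13b, a receptor for B cell survival factors, and Arhgdib, an inhibitor of GDP dissociation. None of these genes passed the threshold of the edgeR test. Of 18210 genes tested with edgeR's quasi-likelihood test, 0 were called higher and 0 lower at a Benjamini-Hochberg adjusted p of 0.05, and the smallest adjusted p was 0.385. At an unadjusted p under 0.05 there were 1463 genes, 751 higher and 712 lower, where 910.5 would be reached by chance. DESeq2 on the same genes called 84 higher and 85 lower, edgeR with no filter on low counts called 183 higher and 117 lower, and limma-voom called 0 in each direction. In 14.7% of genes all treated libraries lay on one side of all controls, against the 10% that chance gives for 3 against 3.

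Kcnj2 (ENSMUSG00000041695, GRCm38 chromosome 11, 111066164 to 111076821, plus strand) was measured at 77.9 ± 9.35 CPM (counts scaled to a common library size; SD, n = 3) in controls and 39.4 ± 3.95 in treated libraries. Its log2 fold change was -0.98 with a standard error of 0.14, an adjusted p of 0.385 in edgeR and 3.07e-07 in DESeq2. Axl (ENSMUSG00000002602, chromosome 7, 25757273 to 25788705, minus strand) was at 43.9 ± 6.27 CPM in controls and 20.8 ± 3.66 in treated libraries. Cd63 (ENSMUSG00000025351, chromosome 10, 128900989 to 128912822, plus strand) was at 1206 ± 188 CPM in controls and 740 ± 39.5 in treated libraries. On the higher side, Gatad2a (ENSMUSG00000036180, chromosome 8, 69907076 to 69996384, minus strand) was at 21.5 ± 0.585 CPM in controls and 38.2 ± 5.09 in treated libraries, a log2 fold change of 0.83 with a standard error of 0.15. Cd74 (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652, plus strand) was at 110.5 ± 12.3 CPM in controls and 209 ± 50.7 in treated libraries. Its exons overlap those of Mir5107. Cd276 (ENSMUSG00000035914, chromosome 9, 58524298 to 58555437, minus strand) was at 8.46 ± 1.29 CPM in controls and 18.2 ± 2.10 in treated libraries, and its exons overlap those of Gm10657. Cirbp, Tnfrsf13b and Arhgdib had log2 fold changes of 0.86, 0.64 and 0.52, and the exons of Arhgdib overlap those of Pde6h. For all 12 of these genes the treated libraries lay on one side of all controls, which the rule for naming them required. Their edgeR adjusted p was between 0.385 and 0.41, and DESeq2, on the same counts, called each gene.

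The interferon-stimulated list, genes induced by type I interferon, fell. Of its 41 measured members 32 had a negative log2 fold change, the median was -0.45, and 15 were lower at an unadjusted p under 0.05 while 0 were higher. In edgeR 0 members passed over all genes and 7 were lower when adjusted over the list alone. DESeq2 called 7 lower. In 14 members all treated libraries lay below all controls, where chance gives 10% for both directions together. Ifitm3, which blocks viral entry, was at 96.0 ± 26.0 CPM (SD, n = 3) in controls and 39.7 ± 9.75 in treated libraries, a log2 fold change of -1.27. It lies on GRCm38 chromosome 7, 141009586 to 141010770, minus strand. Usp18, which removes ISG15 from proteins (chromosome 6, 121245906 to 121270917, plus strand, exons overlapping Gm44148), was at 42.9 ± 10.8 CPM in controls and 19.6 ± 2.46 in treated libraries. Zbp1, a sensor of Z-form nucleic acid, was at 5.37 ± 1.61 CPM in controls and 1.54 ± 0.679 in treated libraries. The camera list test called the list lower with an adjusted p of 1.15e-09 at a preset correlation of 0.01. The adjusted p was 0.376 with an estimated correlation. The mean list level of anti-LILRB4 library 2 was -0.18 (log2, relative to the control mean) and lay above that of control library 2, at -0.28. The median was -0.24 without control library 1, and the list kept its call. With the neutrophil marker level as a covariate the median was -0.21 (adjusted p 0.0396), and with that covariate and without anti-LILRB4 library 2 it was 0.31 (adjusted p 0.0701). Across the 6 libraries the list level followed the neutrophil marker level, with Pearson's r = 0.93 (exact permutation p = 0.00417, adjusted p 0.0208 over the 5 lists compared) and Spearman's rank correlation 0.94 (exact permutation p = 0.0167, adjusted p 0.0833). Without anti-LILRB4 libraries 1 and 3, which lay farthest from the median neutrophil level, r was 0.91. The other 4 lists compared did not pass, with r of 0.67 for disease-associated and 0.69 for mitochondrially encoded (adjusted p 0.191 each), 0.81 for immediate early (adjusted p 0.139) and -0.43 for homeostatic genes (adjusted p 0.372). These permutations moved libraries freely between the treatment groups. Interferon and neutrophil levels were both lower on average in treated libraries, so the p-values do not separate neutrophils from treatment. The comparison was chosen after the levels were seen.

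The disease-associated microglia list, genes raised in microglia around amyloid, also fell. Of 35 measured members 26 had a negative log2 fold change, with a median of -0.27. At an unadjusted p under 0.05, 11 were lower and 0 higher. In edgeR 0 members passed over all genes and 6 were lower when adjusted over the list alone, and DESeq2 called 5 lower. All treated libraries lay below all controls in 7 members, beside the 10% that chance gives for both directions together. Axl and Cd63, above, were the members with the smallest p-values. Other members were at low levels, with Itgax, Spp1 and Gpnmb at 7.14, 10.6 and 0.835 CPM in controls. Their log2 fold changes were -0.44, -1.02 and -1.08, with overlapping groups. How many of the sorted CD45-low cells were in the disease-associated state was not measured. Cd9, a tetraspanin whose exons overlap those of Gm26728, was at 2380 ± 417 CPM (SD, n = 3) in controls and 1593 ± 241 in treated libraries. The camera adjusted p was 4.98e-07 and was 0.376 with an estimated correlation. The median was -0.11 without control library 1, -0.45 without anti-LILRB4 library 1 and -0.42 without anti-LILRB4 library 2, and each of these fits kept the call. With the neutrophil marker level as a covariate the list was no longer called (adjusted p 0.211, median -0.17). Apoe, the lipid carrier, had a log2 fold change of 0.48 (standard error 0.23, adjusted p 0.639 in edgeR), while Trem2, a lipid-sensing receptor, and its adaptor Tyrobp had log2 fold changes of -0.01 and -0.03, whose sign changed when single libraries were left out.

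The homeostatic microglia list, genes of microglia at rest, rose. Of 23 measured members 17 had a positive log2 fold change, the median was 0.11, and 8 were higher and 0 lower at an unadjusted p under 0.05. In edgeR 0 members passed over all genes and 6 were higher when adjusted over the list alone, and DESeq2 called 2 higher. In 8 members all treated libraries lay above all controls, beside the 10% that chance gives for both directions together. Selplg, a selectin ligand, was at 2398 ± 244 CPM (SD, n = 3) in controls and 3589 ± 605 in treated libraries, a log2 fold change of 0.58. Golm1, a Golgi membrane protein whose exons overlap those of Naa35, was at 160 ± 28.0 CPM in controls and 258 ± 65.7 in treated libraries. Cst3, the protease inhibitor cystatin C, had a log2 fold change of 0.45 with overlapping groups. The camera adjusted p was 0.000128 and was 0.376 with an estimated correlation. The lysosome and phagocytosis list was not called, with an adjusted p of 0.544 (camera) and a median of 0.03 over 44 members. In it 1 member, the complement receptor gene C3ar1, was lower when adjusted over the list alone, at 1510 ± 90.7 CPM in controls and 1130 ± 54.3 in treated libraries. Ctss, encoding cathepsin S, and C1qb, a complement component, had log2 fold changes of 0.41 and 0.38.

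**Figure D1:**
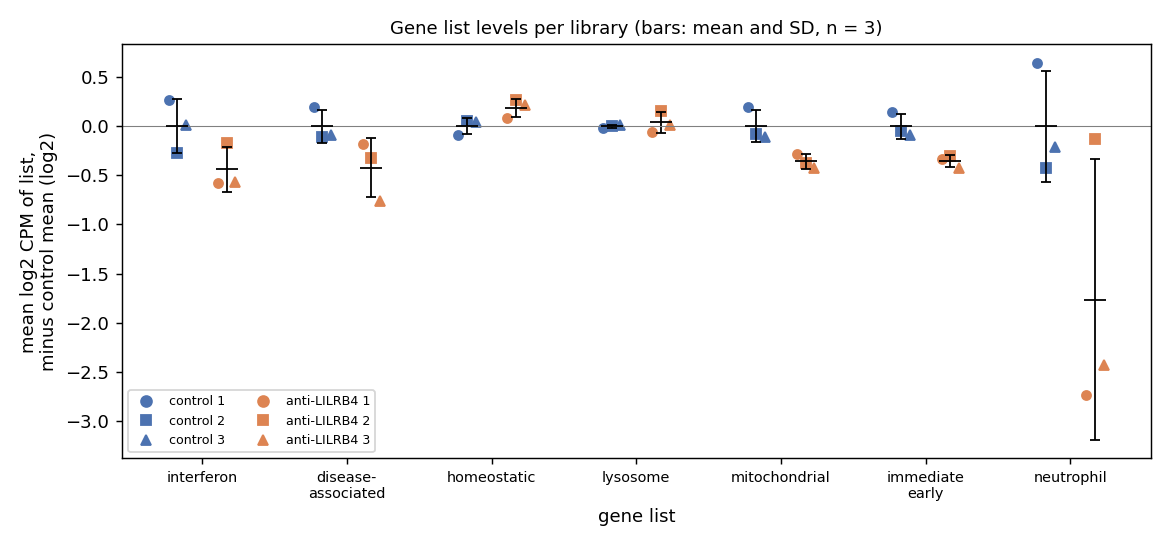
Mean log2 CPM of each gene list per library, with the mean of the 3 control libraries subtracted (y axis, log2), for 7 gene lists (x axis). Points are libraries, bars are the mean and SD of 3 libraries per group. The interferon level of anti-LILRB4 library 2 (-0.18) lay above that of control library 2 (-0.28), and the neutrophil levels of anti-LILRB4 libraries 1 and 3 were -2.73 and -2.43.

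**Figure D2:**
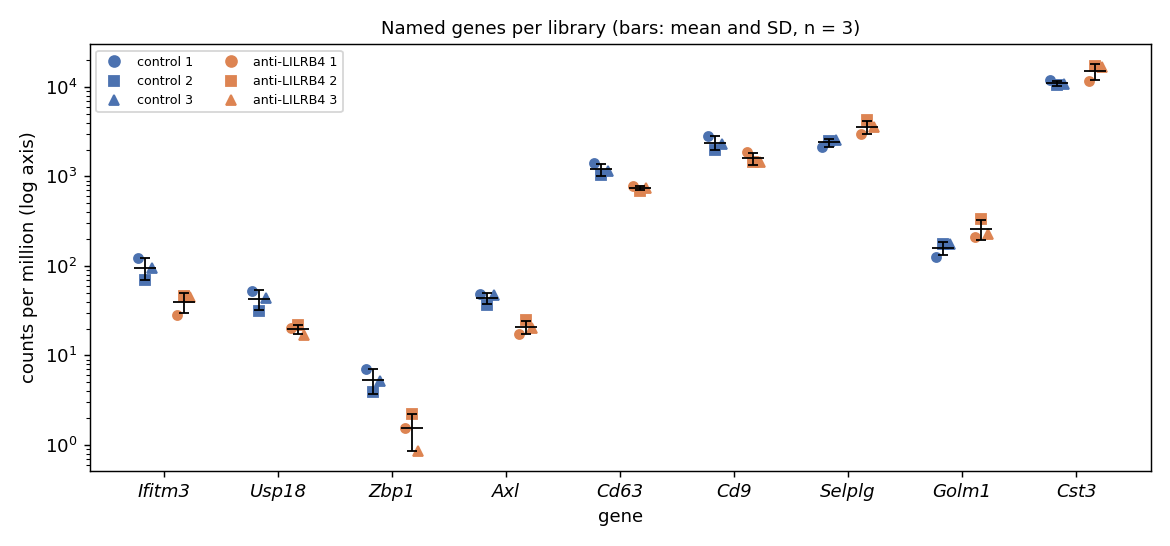
CPM (y axis, log axis) of 9 genes of the interferon, disease-associated and homeostatic lists (x axis) in each library. Points are libraries, bars are the mean and SD of 3 libraries per group. Ifitm3 was at 96.0 CPM in controls and 39.7 in treated libraries, and Selplg at 2398 and 3589.

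Of the 13 secondary lists, 7 were called by camera. The mitochondrially encoded list was lower, with a median of -0.42 over 13 members, 8 of them lower when adjusted over the list alone, and an adjusted p of 1.61e-09 that was 0.376 with an estimated correlation. Its member mt-Cytb was at 5489 ± 301 CPM (SD, n = 3) in controls and 4109 ± 259 in treated libraries. Mitochondrially encoded genes took 4.69, 3.96 and 3.73% of counts in the controls and 3.29, 2.80 and 2.88% in the treated libraries. The immediate early and dissociation list was lower, with a median of -0.25 over 25 members, 5 lower when adjusted over the list alone and an adjusted p of 4.23e-07 (0.0996 with an estimated correlation, as an adjusted p). Klf4, a transcription factor of that list, was at 6.01 ± 0.715 CPM in controls and 2.08 ± 0.541 in treated libraries. The ITIM and ITAM receptor signalling list was higher, with a median of 0.11 over 19 members and an adjusted p of 0.00991, which was 0.376 with an estimated correlation. Its median was 0.19 without control library 2, 0.18 without anti-LILRB4 library 1 and 0.07 without anti-LILRB4 library 3, and it lost its call without control library 3 (adjusted p 0.0508). Inpp5d, encoding the inositol phosphatase SHIP1, was at 276 ± 49.1 CPM in controls and 400.0 ± 79.1 in treated libraries. Cytosolic ribosomal protein genes (median -0.12, adjusted p 0.00991), oxidative phosphorylation genes (median -0.08, adjusted p 0.0168), inflammatory cytokine and NF-kB genes (median -0.14, adjusted p 0.0304) and unfolded protein and integrated stress genes (median -0.12, adjusted p 0.0377) were also called lower. With an estimated correlation their adjusted p was 0.854, 0.854, 0.501 and 0.651. A correction for gene length and GC content ended the oxidative phosphorylation (0.0896, median -0.035) and unfolded protein calls (0.0504, median -0.12), and the neutrophil marker level as a covariate ended the ribosomal (0.265), inflammatory (0.647) and unfolded protein calls (0.152), although their medians with it were -0.11, -0.15 and -0.08. Without control library 1 the median of the ribosomal, oxidative phosphorylation and unfolded protein lists turned to 0.01, 0.02 and 0.02. The inflammatory list lost its call without control library 1 or 3 or anti-LILRB4 library 1 or 3, with adjusted p of 0.241, 0.0759, 0.0921 and 0.0666 and medians of -0.12, -0.13, -0.20 and -0.17, and its median was -0.22 without control library 2. That fit also moved the ribosomal and unfolded protein medians, to -0.20 and -0.18. Without anti-LILRB4 library 2 the ribosomal, oxidative phosphorylation and unfolded protein lists lost theirs too (adjusted p 0.294, 0.910 and 0.261, with the first 2 medians at -0.06 and -0.01), as did the ribosomal and unfolded protein lists without anti-LILRB4 library 1 (0.159 and 0.0544). The oxidative phosphorylation median was -0.14 without anti-LILRB4 library 3. The members of these 4 lists with the smallest p-values were Rpl4, Ndufa10, Ccl12 and Hspa5, with log2 fold changes of 0.42, 0.48, -0.46 and -0.32, so that Rpl4 (exons overlapping Snord16a) and Ndufa10 went against their lists.

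MHC class I, MHC class II, cholesterol synthesis, glycolysis, cell cycle, and lipid efflux and storage genes were not called, with camera adjusted p between 0.208 and 0.893. MHC class I genes were called lower without control library 2 (0.00742) and MHC class II genes higher without control library 1 (0.0250). Mylip, a ubiquitin ligase in the lipid efflux and storage list, had a log2 fold change of -0.38 and was called by DESeq2. The genes with the smallest p-values were H2-M3 in the MHC class I list (log2 fold change -0.52, and -0.30 without control library 1), Pfkl in the glycolysis list (-0.27) and Mki67 in the cell cycle list (3.00, and 1.73 without anti-LILRB4 library 2, at 0.0920 ± 0.0581 CPM in controls).

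Markers of other cell types were measured in the same libraries. Neutrophil markers were called lower by camera, with a median of -0.88 over 10 members and an adjusted p of 3.91e-05, which was 0.486 with an estimated correlation. Relative to the control mean, their levels were 0.64, -0.42 and -0.22 (log2) in controls 1, 2 and 3 and -2.73, -0.13 and -2.43 in anti-LILRB4 libraries 1, 2 and 3. The median was -0.36 without control library 1, -0.44, -2.17 and -0.58 without anti-LILRB4 libraries 1, 2 and 3. Of the 10 members, 0 belong to another of the fixed lists. S100a8, an abundant calcium-binding protein of neutrophils, was at 396 ± 224 CPM (SD, n = 3) in controls and 185 ± 197 in treated libraries, and Ngp at 185 ± 69.7 and 155 ± 196. Border-associated macrophage markers had a median of 0.41 and a camera adjusted p of 0.0710. Their median was 0.25 without anti-LILRB4 library 3 (0.391), and they were called higher without control library 1 (0.0250), without anti-LILRB4 library 2 (0.0369) and with no filter on low counts (0.0405). Monocyte, T and NK cell, B cell, neuron, astrocyte, oligodendrocyte, endothelial and mural, and choroid plexus and ependymal markers had camera adjusted p between 0.153 and 0.908. B cell markers (median 0.34) were called higher without control library 1 (0.000733, median 0.69), without anti-LILRB4 library 2 (0.0201, median 0.16) and with a filter of at least 1 CPM in 3 libraries (0.0409), and had a median of 0.15 without control library 2 (0.924). Without anti-LILRB4 library 2 oligodendrocyte markers were called higher and monocyte markers lower (0.0369 each). The erythrocyte list had fewer than 3 measured members and was not tested.

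The antibody's target was counted as a transgenic row. Human LILRB4 was at 1029, 1031 and 1078 CPM in the controls and at 850, 1304 and 3297 CPM in anti-LILRB4 libraries 1, 2 and 3. Its log2 fold change was 0.80 (standard error 0.38, adjusted p 0.640 in edgeR), and 0.04 without anti-LILRB4 library 3. With no filter on low counts edgeR called LILRB4 and LILRB1 higher (adjusted p 1.41e-08 and 0.00112), while DESeq2 called neither (0.699 and 0.818). The exact permutation test over 10 splits, which cannot go below 0.1, gave a two-sided p of 0.5. In anti-LILRB4 library 3 LILRB1 was at 425 CPM against 108 and 138 in the other treated libraries, LILRA1 at 546 against 177 and 207, and LILRA2 at 2261 against 1159 and 1225. In controls 1, 2 and 3 LILRB1 was at 133, 147 and 158 CPM and LILRA1 at 200, 266 and 249. LILRA2 was at 1904, 1835 and 1861 CPM in controls, so anti-LILRB4 libraries 1 and 2 lay below all controls for LILRA2. These genes are near-identical in parts, so the split of reads between them is uncertain. LILRP1 and LILRP2 were at 3.92 ± 0.910 and 1.22 ± 0.259 CPM in controls (SD, n = 3) and 1.63 ± 0.502 and 1.26 ± 0.484 in treated libraries. The mouse gene Lilrb4a was at 1.68 ± 0.415 CPM in controls and 1.49 ± 0.306 in treated libraries, and the exact permutation test gave a two-sided p of 0.6. Lilrb4b was not analysed here.

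**Figure D3:**
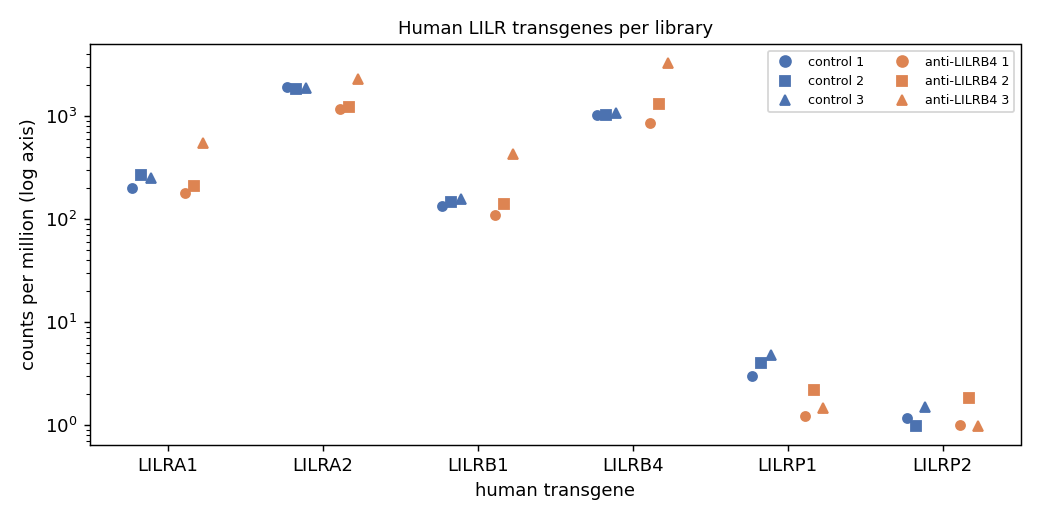
CPM (y axis, log axis) of the 6 human LILR transgene rows (x axis) in each library. Points are libraries. LILRB4 was between 1029 and 1078 CPM in controls and at 850, 1304 and 3297 CPM in the treated libraries.

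The authors' deposited table of the same comparison lists 24870 genes, of which 96 were higher and 91 lower at an adjusted p of 0.05. DESeq2 on the deposited counts of genes with at least 10 reads called 96 higher and 91 lower, and all 187 were also called in the authors' deposited table with the same sign. The edgeR test covered 176 of these genes. All 176 had an unadjusted edgeR p under 0.05 and their median edgeR adjusted p was 0.426.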

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

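The length and GC correction, DESeq2 on genes with at least 10 reads, the permutation of list levels and the neutrophil covariate were chosen after the data were seen. The edgeR counts of 0 higher and 0 lower were the same with DESeq2 size factors, library size only, upper quartile scaling, limma-voom, the CPM filter, robust dispersion, protein-coding genes, an adjusted p of 0.1, a fold change minimum, the length and GC correction, the covariate and each library left out (0 to 0). They became 84 higher and 85 lower with DESeq2, 96 and 91 with DESeq2 on genes with at least 10 reads, and 183 and 117 with edgeR and no filter. Without the filter the estimated prior degrees of freedom were infinite, against 5.92 with it, and 239 of the 300 unfiltered calls were genes of the filtered test. DESeq2 called 103 of the 300. The cause of the DESeq2 difference was not tested on these data, and in the simulation DESeq2 made 59 false calls where edgeR made 14.

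Replicate numbers did not pair the libraries. Deviations of same-numbered libraries correlated at 0.01, 0.03 and -0.01, and with the replicate block 0 genes were called in each direction and 11 lists, as without it. The block changed no list call.

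The same 11 lists were called with DESeq2 size factors, library size only, upper quartile scaling, DESeq2, limma-voom, robust dispersion and protein-coding genes. Values below are adjusted p unless named otherwise. No filter added border-associated macrophage markers (0.0405) and the CPM filter B cell markers (0.0409). With an estimated correlation 0 lists were called. The value was 0.376 for the interferon, disease-associated, homeostatic, ITIM and ITAM, and mitochondrial lists, 0.501 for inflammatory, 0.854 for oxidative phosphorylation and for ribosomal, 0.0996 for immediate early, 0.651 for unfolded protein and 0.486 for neutrophil genes. With fry they were 0.352 for the interferon, disease-associated, homeostatic, and ITIM and ITAM lists, then 0.479, 0.766, 0.785, 0.0816, 0.567 and 0.516 in the order above, and 0.302 for mitochondrial genes. Both take the correlation of the genes from these libraries, and fry compares no other genes. Against the preset 0.01, the estimated correlation was 0.18 for interferon, 0.19 for disease-associated and 0.16 for homeostatic genes. It was 0.50 for mitochondrial, 0.63 for neutrophil and 0.78 for ribosomal genes. For immediate early genes it was -0.0046, under the preset, so a higher correlation did not end that call. Exact permutation of list levels cannot go below 0.1, so for lists at 0.1 the loss of a call says nothing of stability. Its p was 0.1 for the disease-associated, homeostatic, ITIM and ITAM, immediate early and mitochondrial lists, 0.2 for interferon, 0.3 for neutrophil, 0.4 for unfolded protein, 0.6 for inflammatory, and 0.7 for oxidative phosphorylation and ribosomal genes. For the lists above 0.1, other splits of the libraries gave as large a difference in mean level. Mean levels went against the median in the cell cycle (0.7), glycolysis (0.7) and neuron (0.8) lists.

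The length and GC correction ended the calls of oxidative phosphorylation (0.0896) and unfolded protein genes (0.0504) and turned the medians of MHC class II (0.261) and lipid efflux genes (0.509). With the neutrophil covariate the disease-associated (0.211), inflammatory (0.647), ribosomal (0.265) and unfolded protein (0.152) calls ended, with medians of -0.17, -0.15, -0.11 and -0.08 against -0.27, -0.14, -0.12 and -0.12 without it, and the lysosome list and B cell markers (0.0165 each) and monocyte markers (0.0396) were called higher. The medians turned for MHC class I (0.596), MHC class II (0.265), cell cycle (0.265), monocyte (0.0396), neuron, astrocyte and oligodendrocyte (0.699 each) and choroid plexus markers (0.896). The neutrophil list's own median turned from -0.88 to 0.58 and was called higher (7.01e-05), although its level was the covariate. The fit thus did not simply remove the neutrophil difference. Trem2, Tyrobp and LILRA1 turned to log2 fold changes of 0.17, 0.092 and -0.15. Medians also turned for glycolysis with library size only (0.603), T and NK cell (0.714) and choroid plexus (0.337) markers with no filter, and neuron markers with protein-coding genes (0.513). Trem2 turned to 0.0068 with library size only. The cause of these changes was not tested.

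Leaving out 1 library at a time, the adjusted p ranged from 1.46e-15 to 6.47e-06 for interferon, 4.41e-09 to 0.000780 for disease-associated, 1.31e-06 to 0.00576 for homeostatic, 3.86e-09 to 1.38e-06 for mitochondrial and 1.28e-06 to 4.22e-05 for immediate early genes, which kept their calls. It ranged from 0.000619 to 0.0508 for ITIM and ITAM, 0.00122 to 0.241 for inflammatory, 2.01e-07 to 0.367 for ribosomal, 0.000185 to 0.910 for oxidative phosphorylation and 0.000907 to 0.669 for unfolded protein genes, which lost theirs in at least 1 fit, and medians of the last 3 turned without control library 1. Lists with no call whose medians turned ranged from 0.00742 to 0.718 (MHC class I), 0.0250 to 0.477 (MHC class II), 0.0849 to 0.946 (cell cycle), 0.163 to 0.946 (cholesterol synthesis), 0.571 to 0.960 (lipid efflux), 0.371 to 0.823 (glycolysis), 0.0369 to 0.718 (monocyte), 0.380 to 0.946 (T and NK cell), 0.611 to 0.993 (neuron), 0.479 to 0.864 (astrocyte) and 0.0666 to 0.910 (endothelial). Border-associated (0.0250 to 0.391), B cell (0.000733 to 0.924) and oligodendrocyte markers (0.0369 to 0.612) kept their sign and were called in at least 1 fit. Log2 fold changes of genes that turned ranged from -0.32 to 0.053 for Lilrb4a, -0.065 to 0.068 for Trem2, -0.10 to 0.086 for Tyrobp, -0.31 to 0.66 for LILRA1, -0.24 to 0.95 for LILRB1 and -0.30 to 0.22 for LILRP2. At these depths genes under about 1 CPM, such as Mki67, rest on few reads.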

Other observations

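The tests of neutrophil content, of reads moved between LILR genes and of the other splits of the libraries were chosen after the results were seen, and the spread over fits that left out 1 library was added to the length tests after the list levels, but before the corrected values, were seen. Setting each of these fits against its own uncorrected median was chosen after the corrected values were seen, and the reading of the disease-associated and mitochondrial length tests depends on it: against the medians of all libraries, their corrected medians without control library 1 (-0.13 of -0.27 and -0.17 of -0.42) were under the bound of 0.5, which would have left both open. The tests of length and GC, of control library 1 and of other receptors in anti-LILRB4 library 3 were written before their results.

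Border-associated macrophage markers, genes of macrophages at the brain's surfaces, had list levels above all controls in all 3 treated libraries, where chance gives 10% for both directions together. Stab1, a scavenger receptor whose exons overlap those of Nt5dc2, was at 185 ± 35.9 CPM (SD, n = 3) in controls and 251 ± 28.9 in treated libraries, Pf4, a chemokine, was at 14.0 ± 1.46 and 16.7 ± 8.69 with overlapping groups, and the camera adjusted p of the list was 0.0710 (0.0250 without control library 1, 0.0369 without anti-LILRB4 library 2 and 0.391 without anti-LILRB4 library 3). Among B cell markers, Ighm, an immunoglobulin heavy chain, was at 404 ± 8.06 CPM in controls and 515 ± 29.6 in treated libraries and was called by DESeq2 (adjusted p 0.0314), while Cd79b, a chain of the B cell receptor, was at 59.9 ± 23.8 and 80.2 ± 11.9 with overlapping groups and was not called (adjusted p 0.561 in DESeq2).

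The interferon and disease-associated lists were lower in treated libraries at the preset correlation and not called at an estimated one (adjusted p 0.376 each). A trend with gene length and GC content does not account for the interferon list, whose median was -0.44 with the correction and -0.45 without it and was between -0.51 and -0.26 over the fits that left out 1 library; the bound also asked for list levels apart, which the uncorrected levels already missed. Nor does it account for the disease-associated list, whose median went from -0.27 to -0.36 with the correction, with the treated levels still below all controls and an adjusted p of 4.26e-08. Without control library 1 its corrected median was -0.13, where the uncorrected was -0.11, and over the fits that left out 1 library the corrected median was 1.03 to 1.37 times the uncorrected median of the same fit. Fewer neutrophils in the treated sorts, which the CD45-low gate should remove, may account for part of the interferon difference. Anti-LILRB4 library 2, with as many neutrophil transcripts as a control, had an interferon level of -0.18, inside the control range of -0.28 to 0.27. In 14 of the 41 members all treated libraries, this one included, lay below all controls, as for Ifitm3 (46.2 CPM against at least 70.3 in controls). Members were not counted for this library by itself, so that number does not separate neutrophils from treatment. The median with the neutrophil covariate was -0.21, although it ran from -0.41 to 0.31 when 1 library was left out. With that covariate the neutrophil list's own median turned to 0.58, so the medians of that fit are uncertain. For the disease-associated list the median with the covariate was -0.17, from -0.31 to 0.23. The disease-associated level of anti-LILRB4 library 2 was -0.32, below all 3 controls (-0.11 to 0.19). That goes against neutrophils as the whole cause for this list but is 1 library, so neutrophils and treatment cannot be told apart there. An effect of the antibody on microglia stays open, as does one on neutrophils. Of the 10 splits, 3 gave at least 11 called lists (highest other 12), too few splits for a share under 0.05. Every other split also called lists, between 3 and 12, so a camera call at the preset correlation is weaker evidence than its adjusted p. Those splits are not free of treatment, since their groups hold treated and control libraries in unequal number.

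The homeostatic list was higher and the mitochondrially encoded list lower at the preset correlation, and not called at an estimated one (adjusted p 0.376 each). Control library 1, which stood apart on the first principal component, is not the whole cause, since without it the medians were 0.10 and -0.33, against 0.11 and -0.42, and the treated levels lay beyond both other controls. Anti-LILRB4 library 3 stood apart on the second component, at 70.3 where the next highest was 35.3. Without that library the medians were 0.12 and -0.37. With the length and GC correction the medians were 0.076 and -0.28, each 0.68 of the uncorrected, with treated levels still apart from all controls and adjusted p of 0.000123 and 0.000214. For the mitochondrial list the share kept was 0.51 to 0.71 over the fits that left out 1 library, lowest without control library 1 (-0.17 against -0.33, adjusted p 0.0220), which argues narrowly against a length or GC trend as the whole cause but leaves one open for part of it. For the homeostatic list the share was 0.48 without control library 1 (0.046 against 0.096), under the bound of 0.5 set for the test, so such a trend cannot be told apart from treatment at this spread. Differences in cell handling or in treatment may underlie both lists, and handling was not tested apart from treatment. The immediate early and dissociation list was lower in the same comparison (median -0.25, 21 of 25 members negative), with all treated levels below all controls.

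LILRB4 transgene counts differed 3.88-fold among the treated libraries and 1.05-fold among controls. Reads moved between near-identical LILR genes would leave their sum in place, and the sum in anti-LILRB4 library 3 was 6532 CPM, against 2297 to 3352 in the other 5 libraries. The sum was 3269, 3283 and 3352 CPM in controls 1, 2 and 3. In anti-LILRB4 libraries 1 and 2 it was 2297 and 2878 CPM, below all controls. A general rise of myeloid receptors in that library was not seen, since the ITIM and ITAM list had a median log2 ratio of 0.024 to the other treated libraries (quartiles -0.15 and 0.18) where LILRB4 had 1.65. A difference in transgene copy number or expression between mice may be the source and was not tested.

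With 3 against 3 libraries there are 10 splits, so no share can be under 0.05. At an adjusted p of 0.05, edgeR gave 0 genes in the real split and 0 as the highest of the others, so 10 of 10 gave as many. With 0 in the real split no other outcome was possible, so this count says nothing of chance. At an unadjusted p under 0.05 the real split gave 1463 genes and the highest other 1039, and 1 of 10 gave as many. DESeq2 gave 169 genes and at most 26 in the others, and 1 of 10 gave as many. In absolute size the list medians of the real split and the highest of the others were 0.45 and 0.39 for interferon, 0.27 and 0.35 for disease-associated, 0.11 and 0.13 for homeostatic, 0.42 and 0.30 for mitochondrially encoded and 0.25 and 0.18 for immediate early genes, so 3 of 10 splits gave a median as large for the disease-associated list, 2 of 10 for the homeostatic list and 1 of 10 for each of the others.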
